A study of Danio rerio with 19 samples.

How the data were processed

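Liver RNA of F1 zebrafish of the AB line, 4 months old, was measured on 19 one-colour Agilent arrays. Per the labels, the fish had lived in water with 5-fluorouracil (5-FU) at nominal concentrations of 0.01 or 1 µg/L, or with the vehicle dimethyl sulfoxide alone (1 µL/L), with renewal of the medium every 3 days. The vehicle content of the dosed tanks is not given. Each treatment had 2 tanks with 10 livers taken from each, and the tank of each array is not given. The arrays form 6 groups by dose and sex: 3 arrays each, and 4 for females at 1 µg/L. An array holds a pool of 3 fish (14 arrays), a pool of 2 (4 arrays) or a single fish (1 array, females at 1 µg/L, replicate 4). The pools are the replicates, so the p-values of single genes measure the spread between pools. No p-value takes account of the tank.

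Per the file headers, the arrays carry design 026437 with the zebrafish annotation danRer7 (Zv9), and the authors scanned them with Agilent Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09. The deposited scanner values are intensities on a linear scale: the processed Cy3 signal (background subtracted, detrended within the array, with a surrogate for signals not above background), the mean spot signal and the local background. The authors' value table holds log2 values, made with R 2.15.1 and limma per the submitters' processing notes. Its normalization method is not stated, and the medians of its arrays lie between 5.80 and 6.07. The table was used only as an alternative.

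Each array has 45220 spots, 43803 of them not controls, for 43603 probes. Between 65.8% and 83.3% of probes were well above background on an array, no spot was saturated, and 2 to 27 spots per array were marked as outliers. The 75th percentile of the processed signal ran from 240.2 to 870 over the arrays and was higher in males (391.4 to 870) than in females (240.2 to 411).

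The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Outlier spots were set missing and repeated spots of a probe were averaged. Probes well above background on at least 3 of the 19 arrays were kept (36925), and each gene was represented by its brightest probe (21947 genes, 9199 of them with several probes). Probes were named by systematic name (25854), an accession in the file (2054), a current symbol (4180) or an older symbol (842), and 10673 kept the name of the file. The gene table used for names comes from assembly GRCz12tu; no position was taken from it.

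All arrays entered a single limma 3.58.1 fit (R 4.3.3) with 1 mean per group, empirical Bayes moderation with default settings and Benjamini-Hochberg adjustment over all genes of a contrast. Genes were called at an adjusted p under 0.05. The 10 contrasts were each dose against control over both sexes (the mean of the female and male differences), 1 against 0.01 µg/L, each dose within each sex, the difference of each dose's effect between the sexes, and control females against control males. The residual degrees of freedom were 13, with 2.43 more from the prior. Fold changes are log2 values, and SE is the moderated standard error.

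A set of 32 gene lists was fixed before the data were examined. The result of 1 list is not given. The others cover DNA repair, cell cycle, pyrimidine and folate metabolism, ribosome biogenesis, ribosomal proteins, xenobiotic metabolism, antioxidant response, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glucose metabolism, bile acid metabolism, and vitellogenins and estrogen response. They also cover acute phase and complement, interferon response, secreted hepatocyte proteins, unfolded protein and amino acid stress, heat shock proteins, apoptosis, oxidative phosphorylation and circadian clock. The rest are markers of exocrine pancreas, endocrine pancreas, intestine, erythrocytes, myeloid cells, lymphoid cells, oocytes and ovary, bile ducts, endothelium and stellate cells, and muscle. Lists were tested with camera (limma) at its preset inter-gene correlation of 0.01, with adjustment over the 32 lists, and again with an estimated correlation and with fry. Camera sets the genes of a list against the other genes. At the preset correlation it treats them as nearly independent, although estimated correlations reached 0.906 (ribosomal proteins). Its p-values at the preset correlation therefore do not measure the spread between pools. Genes with a missing value (91) were left out of the list tests. A list score is the mean over a list's genes of the log2 signal minus each gene's mean over the arrays.

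The rule for named genes was fixed before the data were examined. It takes genes with a symbol: for each dose over both sexes the 10 largest rises and the 10 largest falls among called genes with the same sign in both sexes, for the other dose contrasts the 5 largest each way, for the sexes the 10 largest each way, and up to 4 members of each list by smallest p. For a gene not well above background in a whole group, a lower bound of the fold is given as "at least". It sets the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the gene's own signal and the lowest signal among probes well above background on that array.

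The fit was tested on simulated data with known changes, and it made calls at these group sizes. Alternatives covered background correction, scaling, filters, probe summaries, moderation, weights, models, blocks, the authors' table, the threshold and each array left out in turn. The other background correction, normexp, added an offset of 50 to each signal before the log2 scale. The median processed signal of an array was 33.35 to 122.55. The offset therefore shrinks fold changes of dim genes by construction. Another 3 alternatives were chosen after the data were seen. The arrays lie on 5 slides, each scanned in 1 run. No slide holds control and dosed arrays of the same sex, and the control females have a slide to themselves. A fit with slide as a fixed block was therefore possible for the male contrasts and for 1 against 0.01 µg/L alone. Control males shared their slide only with replicate 1 of the females at 0.01 µg/L, whose scanner quality value was out of range. Males at 1 µg/L shared theirs only with the single fish. The blocked male contrasts therefore rest on single female arrays. Results for both doses share their control arrays. Replicate numbers did not pair the arrays as a whole: of 45 pairs with the same number, 18 had a correlation of deviations over 0.1 (median 0.04), and 8 of 19 arrays correlated best with an array of their own number. All same-number pairs were over 0.1 between females of control and 0.01 µg/L (0.18 to 0.6) and between males of both doses (0.22 to 0.34).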

Results

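In livers of zebrafish kept at 1 µg/L 5-FU, several genes of fat synthesis and of fat oxidation changed, in opposite directions. The glucokinase gene *gck*, the acetyl-CoA carboxylase gene *acaca* and the lipogenic genes *thrsp* and *mid1ip1l* fell, and the mitochondrial oxidation genes *hadhaa*, *hadhab* and *acaa2* rose. The antiviral gene *mxb* and the sterol exporter gene *abcg8* rose as well, and *cyp7a1*, the first enzyme of the main bile acid pathway, fell. In males alone *mxb* did not pass. These changes cannot be told apart from differences between slides, since no slide held control and dosed arrays of the same sex. At 0.01 µg/L, against the same control arrays, fewer genes passed.

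At 1 µg/L, over both sexes, 1845 of 21947 genes passed an adjusted p of 0.05 in the limma fit, 732 higher and 1113 lower than control. The share of higher genes was 39.7%. It was 19% after a different background correction (normexp with an offset of 50), 46.6% with median scaling and 48.8% in the authors' value table. Neither direction is therefore reported as the larger. Values in brackets are log2 fold changes with SE and adjusted p. The 10 largest falls among named genes took in metabolic enzymes: *gck*, the liver's glucose sensor kinase (-3.90, SE 0.73, adjusted p 0.00595), *thrsp*, which drives lipogenesis (-3.41, SE 0.90, 0.0305), *acaca*, which makes malonyl-CoA (-3.18, SE 0.59, 0.00591), *aacs*, which activates acetoacetate for lipid synthesis (-2.83, SE 0.81, 0.0428), and *cyp7a1* (-2.81, SE 0.59, 0.0107). The others were *slbp2*, a histone mRNA binding protein (-4.46, SE 1.06, 0.019), the complement factor gene *bfb* (-3.22, SE 0.69, 0.0112), *zwi* (-3.27, well above background on 2 of 4 arrays of dosed females), *lrit3a* (-2.96, at least 4.95-fold lower, not well above background in dosed females) and *klhl41b*, a muscle protein (-2.69). With the array scores of oocyte and intestine markers as covariates, *slbp2* (-2.65, adjusted p 0.145), *zwi* (-2.86, 0.156), *bfb* (-3.20, 0.0618), *klhl41b* (-3.05, 0.0729), *lrit3a* (-2.58, 0.0913) and *aacs* (-2.79, 0.138) no longer passed. *gck*, *thrsp*, *acaca* and *cyp7a1* passed with these covariates too. With each array left out in turn, *gck*, *acaca* and *cyp7a1* passed all 19 times, *thrsp* 13 times and *aacs* 3 times. The count was 976 without replicate 1 of the males at 1 µg/L, 1074 without their replicate 3, and 1100 without control male 1.

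**Figure D1:**
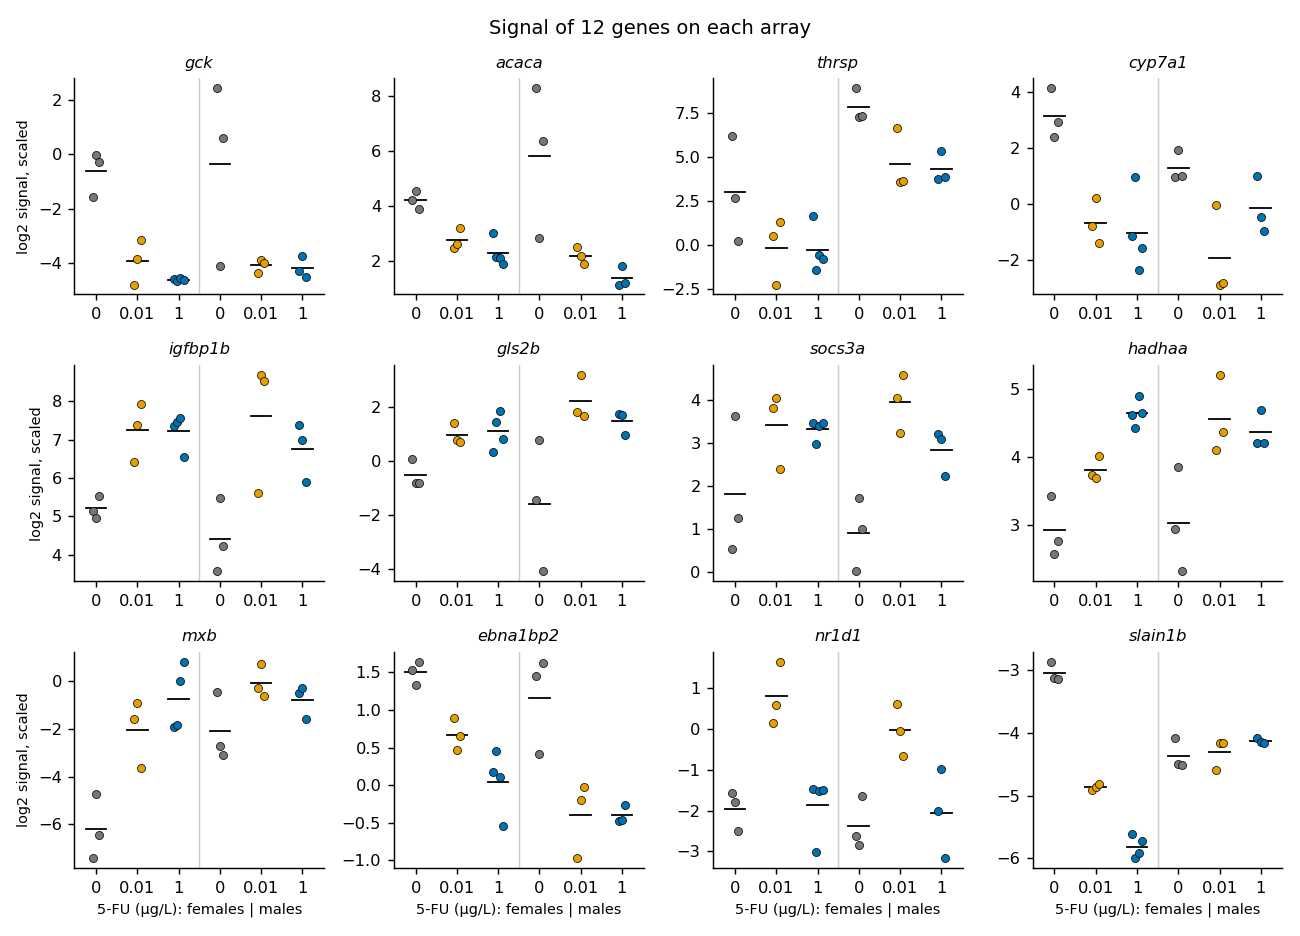
Log2 signal, scaled to each array's 75th percentile (y axis), of 12 genes on the 19 arrays (points) by 5-FU dose in µg/L (x axis; females left of the grey line, males right; black lines are group means). *gck* fell and *igfbp1b* and *hadhaa* rose at both doses, *acaca* and *thrsp* fell at 1 µg/L and did not pass at 0.01 µg/L (adjusted p 0.0573 and 0.101), and *slain1b* fell in females.

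The 10 largest rises at 1 µg/L began with *mxb*, an interferon-induced GTPase (3.38, SE 0.63, adjusted p 0.00591), and held a relative of it in immune defence, *irge4* (2.06, 0.0267). Enzymes of lipid and amino acid handling followed: *gba2*, which cleaves glucosylceramide (2.5, SE 0.41, 0.00322), *etnk2*, which phosphorylates ethanolamine (2.07, 0.0192), and *gls2b*, a glutaminase (2.36, SE 0.58, 0.0219). *igfbp1b*, which binds insulin-like growth factors and rises on fasting in vertebrate liver, rose by 2.18 (SE 0.48, 0.0133). The Notch ligand gene *jag1a* (2.08, 0.00936), *ntd5* (2.14, 0.00922), the guanine exchange factor gene *vav2* (2.01, 0.036) and the catenin gene *ctnnd2a* (2.01, 0.00953) completed the group. With the oocyte and intestine covariates *mxb* (2.77, adjusted p 0.0626), *irge4* (1.16, 0.255), *gls2b* (2.46, 0.0838), *etnk2* (1.51, 0.139) and *vav2* (1.3, 0.117) fell short of the threshold. The controls of *gba2*, *vav2* and, in females, *mxb* lay close to background, and with normexp the changes were 0.3 (adjusted p 0.0779), 0.1 (0.574) and 1.49 (past the threshold), the lowest of their alternatives (up to 2.74, 2.33 and 3.79). The offset of normexp shrinks the changes of such dim genes by construction. Of 93 genes named for any comparison that passed at 1 µg/L, 79 lay on the same side of the control mean of their sex on all 7 dosed arrays. These genes had passed on the same arrays, so this agreement follows largely from how they were chosen. No slide held control and dosed arrays of the same sex, so dose and slide could not be separated in females, and in males only through a block.

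Among metabolic lists, fatty acid oxidation had the clearest members at 1 µg/L. Of 35 genes, 8 rose, 1 fell and 26 did not pass (adjusted over the list alone, 13 rose and 3 fell). The median was 0.36, with 0.57 in females and 0.12 in males. *hadhaa* (1.53, SE 0.25, adjusted p 0.00288), *acaa2* (1.00, 0.00595), *hadhab* (0.56, 0.0126) and *etfdh* (0.86, 0.0144), all steps of the mitochondrial pathway, rose, as did *hadhb* (0.90), *acadvl* (1.31), *hadh* (0.66) and *cpt1aa*, the entry step (1.05, 0.0425). The one fall was *pdk4*, a pyruvate dehydrogenase kinase (-0.85, 0.0261). The list was called by camera (adjusted p 0.000215; 0.958 with an estimated correlation). Fatty acid synthesis had 5 falls and no rise among 26 genes: *acaca*, *thrsp*, *mid1ip1l*, which activates the carboxylase (-1.61, 0.00549), the citrate carrier *slc25a1b* (-0.76, 0.0195) and the elongase *elovl5* (-0.61, 0.046). Adjusted over the list alone, 10 fell and 2 rose. Its median was -0.37 and camera did not call it (adjusted p 0.185). *fasn* (-1.78, 0.0769) and *scd* (-2.86, 0.0937) did not pass. These last genes and *hadhb*, *acadvl*, *hadh*, *cpt1aa*, *etfdh*, *pdk4* and *elovl5* lie outside the rule for named genes and were named after their values were seen. In glucose metabolism *gck* and the tyrosine aminotransferase *tat* (-1.07, 0.0241) fell and *igfbp1b* rose, with 33 of 36 genes not passed and a camera adjusted p of 0.474. No gene of cholesterol synthesis passed (26 genes, median -0.25).

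Bile acid genes moved apart from each other at 1 µg/L: *cyp7a1* fell, while *hsd3b7*, the next ring-modifying enzyme (1.53, SE 0.27, adjusted p 0.00484), *abcg8*, a sterol exporter subunit (1.12, 0.00336), and *amacr*, a side-chain racemase (0.56, 0.0108), rose. The list's median was 0.22 (camera adjusted p 0.16). In xenobiotic metabolism *gstt1a* (-1.02, 0.0448) and the sulfotransferase *sult2st2* (-0.88, 0.0443) fell and 47 of 49 genes did not pass. In antioxidant response *nfe2l2a*, the Nrf2 gene (-0.90, 0.00946), and *srxn1* (-0.59, 0.0358), one of its targets, fell, and 28 of 30 genes did not pass.

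The drug blocks thymidylate synthase and enters RNA and DNA. At 1 µg/L few genes passed in the lists of pyrimidine and folate metabolism, DNA repair, cell cycle and apoptosis. In pyrimidine and folate metabolism the nucleotidase gene *nt5c3a* fell (-0.96, 0.00953) and 35 of 36 did not pass. In DNA repair *rad23b* rose (0.64, 0.00879), in cell cycle *bub3* fell (-0.77, 0.0475), and in apoptosis *casp2* fell (-0.74, 0.00941) and *bcl2a* rose (0.73, 0.0156). The medians of these lists were -0.20, -0.15, -0.35 and 0.03, and camera called none of them (adjusted p 0.564, 0.67, 0.474 and 0.394). In the simulated data 43 of 100 genes with a log2 fold change of 1 were recovered in this contrast, so smaller shifts of such genes were often not detectable.

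Some genes of protein production fell at 1 µg/L, where 1113 of all 21947 genes fell. The falls that passed among ribosomal proteins (1 of 44), unfolded protein and amino acid stress (2 of 40) and heat shock proteins (2 of 35) did not exceed that share by much. Ribosome biogenesis, whose products are assembled on the rRNA that 5-FU can enter, had 4 falls and no rise among 34 genes: *ebna1bp2* (-1.50, SE 0.22, adjusted p 0.00212), *nhp2* (-1.18, 0.0137), *utp3* (-0.88, 0.0296; named after its value was seen) and nucleolin, *ncl* (-0.67, 0.0453). Camera called the list (median -0.34, adjusted p 0.00385; 0.958 with an estimated correlation). Ribosomal proteins were lower by little (median -0.24, 41 of 44 members lower, adjusted p 0.000261; 0.958 with an estimated correlation), with *rps6* (-0.56, 0.0272) the one fall that passed. In the unfolded protein and amino acid stress list *sec61a1a* (-0.65, 0.0296) and *atf5b* (-0.92, 0.0294) fell and *dnajb9a* rose (0.94, 0.0459), with a median of -0.47 (-0.78 in females and 0.02 in males; adjusted p 0.00258, 0.958 with an estimated correlation). Among heat shock proteins *hsph1* (-1.08, 0.0144) and *hspa9* (-0.71, 0.0316) fell (median -0.17, adjusted p 0.244).

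Several immune and blood genes rose at 1 µg/L, where 732 of all 21947 genes rose. The rises among myeloid markers (2 of 36), lymphoid markers (1 of 22) and acute phase genes (1 of 44) were near that share. They are thus no sign of a response of those lists. In interferon response *mxb*, *mxe* (1.46, adjusted p 0.0435), *irf9*, part of the factor that transmits the interferon signal (0.60, 0.0411), and *ifi35* (0.84, 0.0363) rose, *mxc* (named after its value was seen) fell (-0.55, 0.0484) and 26 of 31 did not pass (adjusted over the list alone, 9 rose and 1 fell). The median was 0.98, with 1.4 in females and 0.36 in males (camera adjusted p 5.2e-07, or 0.958 with an estimated correlation). Among myeloid markers *lcp1* (0.80, 0.0183) and *csf1ra*, the macrophage growth factor receptor (0.69, 0.0351), rose (median 0.42, adjusted p 0.000227; 0.958 with an estimated correlation). The lymphoid marker *prdm1a* (1.51, SE 0.27, 0.00466), the adult globins *hbaa2* (1.88, 0.0453) and *hbba2* (1.57, 0.0367) and the suppressor of cytokine signalling *socs3a* (1.72, 0.0316) rose too, in lists that camera did not call (adjusted p 0.185, 0.185 and 0.715). Of the remaining lists, those of secreted hepatocyte proteins (*ttr* up, 0.90; *fah* down, -0.66), oxidative phosphorylation (*ndufv1* up, 0.52; *cox4i2* down, -0.75), circadian clock (*clockb*, -0.84, and *bhlhe40*, -0.84, down, the latter named after its value was seen), bile duct markers (*cldn3d* up, 0.80), and endothelial and stellate markers (*lrata*, -1.31, and *plvapa*, -0.76, down) had 1 or 2 genes past the threshold. Vitellogenins, muscle and both pancreas lists had none, and camera called none of these (adjusted p 0.2 to 0.947).

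Markers of other tissues varied between arrays. At 1 µg/L the oocyte and ovary markers were lower (median -2.29, 39 of 41 members lower, adjusted p 3.46e-07; 0.958 with an estimated correlation) and the intestine markers higher (median 2.34, adjusted p 0.000461; 0.958 with an estimated correlation), yet of their 41 and 19 genes only *dnd1*, a germ-cell gene, passed (-1.75, SE 0.37, 0.0104). The oocyte score ran from -2.67 to 3.34 over the arrays, with values of 2.2 in a control male and 3.34 in a control female, and the intestine score from -4.55 to 1.97. Exact permutation of the arrays within sex (two-sided) gave p = 0.0343 for the oocyte score and 0.104 for the intestine score at 1 µg/L. Of 100 splits of the same arrays within sex, 95 called as many lists as the 8 called at 1 µg/L, and 93 as many as the 7 at 0.01 µg/L, so the list calls cannot be told from those of other groupings.

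**Figure D2:**
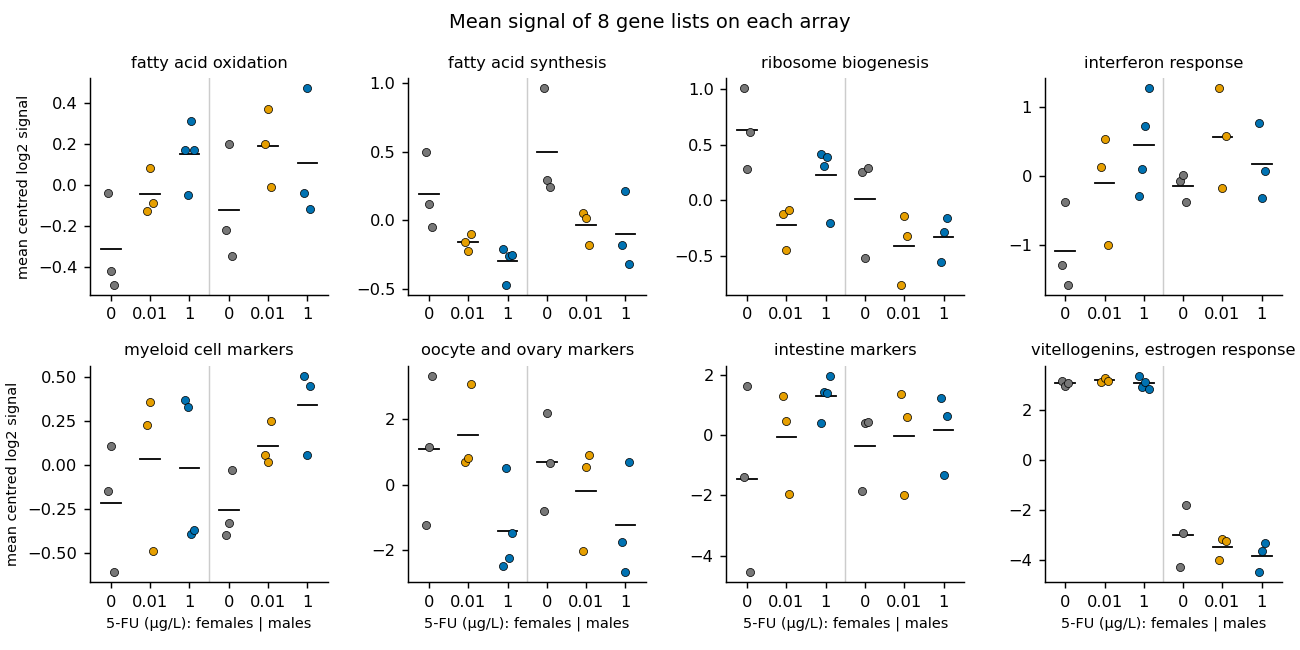
Mean centred log2 signal of 8 gene lists (y axis) on the 19 arrays (points) by 5-FU dose in µg/L (x axis; females left of the grey line, males right; black lines are group means). Oocyte and intestine scores spread over several log2 units within groups, from -2.67 to 3.34 and from -4.55 to 1.97, and vitellogenins part the sexes at each dose.

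At 0.01 µg/L, over both sexes, 227 genes passed, 84 higher and 143 lower (37% higher; 54.1% with median scaling and 55.6% in the authors' table, so neither direction is reported as the larger). The largest rises included *mxb* (3.09, SE 0.65, adjusted p 0.0393), *gls2b* (2.66, SE 0.60, 0.046), *igfbp1b* (2.61, SE 0.50, 0.0246), *nr1d1*, a repressor of the circadian clock (2.55, SE 0.41, 0.0163), and *socs3a* (2.32, SE 0.47, 0.0325). *ctnnd2a* (2.23), the lipase-like *abhd3* (2.06), *myca*, the Myc growth regulator (1.92, SE 0.27, 0.0159), *filip1l* (1.91, its probes disagree) and the chemokine gene *ccl35.2* (1.80, 0.0197) followed. The largest falls were *cyp7a1* (-3.52, SE 0.61, 0.0207) and *gck* (-3.51, SE 0.75, 0.0407), then the transcription factor gene *zbtb16a* (-2.85, 0.0425), the small heat shock gene *cryabb* (-2.66, at least 1.68-fold lower, not well above background in dosed fish), *myo3a* (-2.48, at least 3.51-fold lower) and the folate carrier *slc25a32a* (-2.41, 0.0437). *th2* (-2.08, 0.0233), *nmur1b* (-2.03, at least 2.60-fold lower), *nrn1b* (-1.93, not well above background in 3 of the 4 groups) and *pdk3b* (-1.92, at least 2.05-fold lower) completed them. *myca* passed with each of the 19 arrays left out in turn, *nr1d1* with 18, *cyp7a1* and *abhd3* with 17, *gck* with 4 and *gls2b* with 1. Without the low-dose female array of replicate 2 the count was 13, without the control male array of replicate 2 it was 961, and without the 3 arrays whose scanner quality value was out of range it was 1.

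Ribosome biogenesis genes were lower at 0.01 µg/L: 32 of 34 genes were lower (median -0.65), 2 passed over all genes, *ebna1bp2* (-1.19, SE 0.23, adjusted p 0.0289) and *nop2* (-1.23, SE 0.28, 0.0461), and 24 passed adjusted over the list alone. Camera called it (4.36e-11; adjusted p 0.824 with an estimated correlation). The unfolded protein and amino acid stress list was lower (median -0.54, adjusted p 0.000408; 0.874 with an estimated correlation), although its one called member, the chaperone *dnajb9a*, rose (1.3, 0.0407). The interferon list was higher (median 0.93, 29 of 31 members; adjusted p 1.69e-10, 0.824 with an estimated correlation), with *mxb* alone past the threshold and *mxa* (1.34, 0.0545) short of it. Fatty acid oxidation was higher (median 0.29, adjusted p 3.26e-06; 0.824 with an estimated correlation): *hadhaa* rose (1.21, 0.0393), and *pparab*, a receptor that switches these genes on, fell (-1.50, 0.0407). Erythrocyte (median 0.61, adjusted p 4.46e-06), myeloid (0.27, 0.000173) and intestine markers (0.74, 0.0148) were called higher with no member passing, and not with an estimated correlation (adjusted p 0.824, 0.874 and 0.89). The oocyte markers were not called (median -0.14, 0.54 in females and -0.84 in males, adjusted p 0.762). In other lists *slc25a1b* (-1.10, 0.0203) and *rorcb*, a clock gene (-1.10, 0.0431), fell, and *hsd3b7* (1.4, 0.0306), *prdm1a* (1.53, 0.0226) and *cyp3c1* (0.64, 0.0467) rose. *acaca* (-2.54, 0.0573) and *thrsp* (-3.19, 0.101) did not pass. The 25 lists not called had adjusted p from 0.0821 to 0.986, with no gene called among DNA repair, cell cycle, pyrimidine and folate metabolism, or apoptosis.

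**Figure D3:**
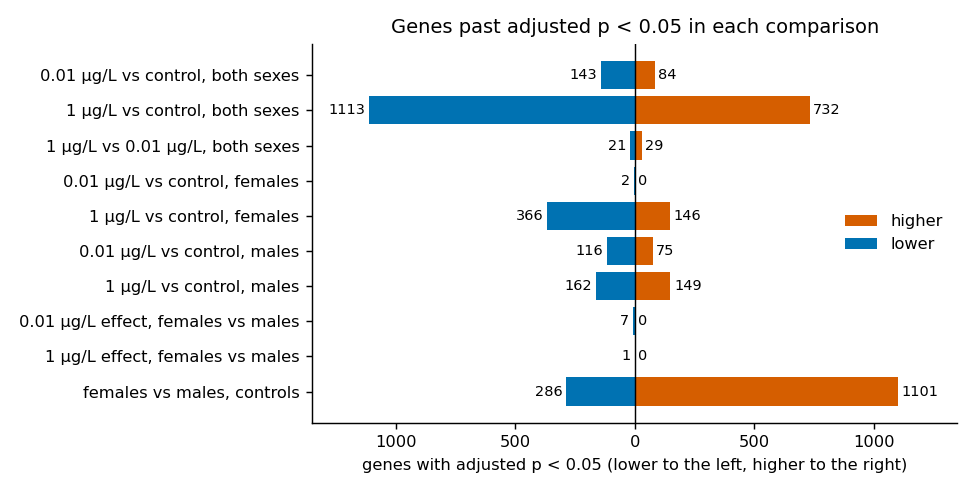
Number of genes (x axis) with an adjusted p under 0.05 in each of the 10 comparisons (y axis), higher to the right and lower to the left. The 1 µg/L contrast over both sexes had 732 higher and 1113 lower, against 84 and 143 at 0.01 µg/L.

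The doses overlapped: 67 genes were called higher and 87 lower at both, where independent lists would share 2.80 and 7.25, and no gene was called in opposite directions. *mxb*, *gls2b*, *igfbp1b*, *ctnnd2a*, *socs3a*, *myca*, *cyp7a1*, *gck* and *hadhaa* were among the genes called at both. Both contrasts used the same control arrays, which by itself makes fold changes alike, so how much of the overlap goes with the dose is not shown. Data simulated with no effect and shared controls had at most 1 gene in common in each direction, but called a median of 0 genes at each dose, so they put no bound on an overlap of longer lists. The fold changes of the doses correlated at 0.606 over 21856 genes (genes are not independent replicates), and data simulated with no effect gave 0.50 (range -0.105 to 0.903). With the controls split so that no control array served both doses, the correlation was 0.216 (median of 36 splits, 0.015 to 0.489). The covariance was 0.226 against 0.095 with no effect (range -0.012 to 0.281), and 75.76% of genes had the same sign at both doses against 67.4% (43.8 to 82.1). All 3 observed values lay within the range with no effect.

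Between 1 and 0.01 µg/L 50 genes differed, 29 higher and 21 lower at 1 µg/L (58% higher; 46.3% in the authors' table and 85.7% of 7 genes with median scaling). *nr1d1* was lower at 1 µg/L (-2.35, SE 0.40, adjusted p 0.0355), where it stood at the control level (0.20, 0.783). The ubiquitin ligase *rnf19a* (-2.48, 0.0355), *mhc1ze* (-2.26, 0.0478), *znf395b* (-1.54, 0.0355) and the kinase *pim1* (-1.13, 0.0338) were lower too. The apolipoprotein gene *apof* (2.72, at least 3.92-fold), the connexin *gja2* (2.16, 0.0477), *cltrn* (1.83, 0.0478), *lrp11* (1.78, at least 1.86-fold) and *adam9b* (1.58, its probes disagree) were higher. With slide as a block 3 genes passed, none of them among the 50. With the replicate number as a block 7 genes passed. Without replicate 3 of the females at 1 µg/L the count was 2, and without their replicate 2 it was 98.

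In females at 1 µg/L 512 genes passed, 146 higher and 366 lower (28.5% higher, against 49.6% with median scaling and 50.5% in the authors' table). *mxb* (5.46, SE 0.86, adjusted p 0.0195), *irge4* (3.31, 0.0303), *mxe* (2.63, 0.0296), *gba2* (2.67, 0.0273) and *ntd5* (2.62, 0.0363) rose most, although with normexp *mxb* was 2.11 (adjusted p 0.0709; 2.11 to 6.2 over its alternatives) and *gba2* 0.27 (0.372; 0.27 to 3.15). *mhc1ze*, an antigen-presenting gene (-4.21, SE 0.60, 0.0111), *cyp7a1* (-4.18, 0.0224), *gck* (-3.98, 0.0488), the methionine enzyme *mat2ab* (-2.84, 0.0363) and the threonine enzyme *tdh* (-2.84, 0.0303) fell most. Without replicate 3 of this group the count was 45. In females at 0.01 µg/L 2 genes passed, *slain1b*, a microtubule regulator (-1.82, at least 3.49-fold lower, 0.00121), and wu:fc03g10, named outside the rule after its value was seen. The count at an unadjusted p under 0.05 was 2363.

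In males at 1 µg/L 311 genes passed, 149 higher and 162 lower (47.9% higher, 22.1% with normexp). *acaca* fell most among named genes (-4.43, SE 0.87, adjusted p 0.0243), with *gatm*, the first enzyme of creatine synthesis (-3.35, 0.0192), the sodium channel subunit *scn4bb* (-2.70, 0.00996), *asb11* (-2.50, 0.0239) and *ankrd31* (-3.40, at least 3.79-fold lower). The relaxin gene *rln3a* (4.42, at least 7.94-fold higher, 0.00996), the chemokine genes *ccl34a.4* (3.23, 0.0379) and *ccl35.2* (3.20, 0.00758), *ccn6* (2.97, at least 1.81-fold; -0.16 with normexp) and *ctnnd2a* (2.90, 0.0324) rose most. At 0.01 µg/L 191 genes passed, 75 higher and 116 lower (39.3% higher; 56.4% with median scaling and 58.8% in the authors' table). *gls2b* (3.82, 0.0471), *ctnnd2a* (3.36, 0.0309), *rln3a* (3.24, at least 3.51-fold, 0.0461), *igfbp1b* (3.19, 0.0468) and *socs3a* (3.04, 0.0468) rose most, and *cryabb* (-3.71, at least 3.33-fold lower), *myo3a* (-2.98, 0.049), *lrp11* (-2.84, at least 2.09-fold lower), *rcan3*, a calcineurin regulator (-2.77, 0.021), and *tmeff2a* (-2.64, at least 1.89-fold lower) fell most. Without control male 1 the counts at 1 and 0.01 µg/L were 9 and 0, and without control male 2 they were 929 and 998. The male doses shared 34 higher and 67 lower genes. With slide as a block 6 male genes passed at 1 µg/L, none of them among the 311, and 0 at 0.01 µg/L in limma, and *acaca* stood at -3.85 (adjusted p 0.998). This block joins the male groups only through single female arrays, so the lost calls do not show that slide was the source.

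Few genes passed the test of a dose effect that differs between the sexes. This test has larger standard errors than those within a sex, and no such difference was simulated. The few calls therefore do not show that the effects were alike. At 1 µg/L *slain1b* alone passed the test of the difference (-3.01, SE 0.26, adjusted p 9.36e-05): -2.77 in females and 0.24 in males. It was not well above background in dosed females, so the difference is given as at least 6.51-fold, and with normexp it was -0.3 (adjusted p 0.853; -3.15 to -0.3 over all alternatives). At 0.01 µg/L 7 genes passed the test of the difference, each lower in dosed females than in dosed males relative to control, among them *slain1b* (-1.89, at least 3.64-fold, 0.0296), *smtla* (-3.77, at least 8.87-fold, 0.0296), *nmd3*, a ribosome export factor (-2.2, 0.0475), and *nptna* (-2.78, its probes disagree). No gene passed in limma with normexp, median scaling or a replicate block, none of the 7 passed with quantile normalization, and the count moved by over 1.5 times without any of 17 of the 19 arrays. At 1 µg/L 25 genes were called higher and 42 lower in both sexes, and none in opposite directions. *mxb* rose by 5.46 in females and by 1.31 in males (not passed, 0.514), and the difference was not past the threshold (4.16, SE 1.26, 0.442).

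Yolk genes were among those that differed between the sexes. In controls 1387 genes differed, 1101 higher in females and 286 higher in males (79.4% higher in females, 67.8% after quantile normalization and 67.3% in the authors' table), or 706 without control male 1. The yolk precursor genes *vtg3* (10.79, SE 0.71, adjusted p 1.35e-07), *vtg2* (8.12), *vtg5* (7.61), *vtg4* (7.11) and *vtg6* (6.82) and the egg-yolk protease gene *nots* (10.58, SE 0.57, 1.97e-08) were higher in females, with *supt3h* (9.64), *crebbpa* (9.51, its probes disagree), *eevs* (6.92) and *irgf4* (6.77, at least 24.7-fold). *hsd17b3*, an androgen-making enzyme (-6.91, SE 0.54, 1.15e-06), *trim35-9* (-6.38, at least 40.8-fold), the elongase *elovl6* (-5.11, 0.00416), *cldn11a* (-4.98), *rgra* (-4.91, at least 8.26-fold) and *thrsp* (-4.78, 0.0414) were higher in males, as were *lrit3a* (-4.43), *mhc2d8.35b2* (-4.16, its probes disagree), *mxb* (-4.10, 0.0145) and *pimr128* (-4.09, at least 5.50-fold). No vitellogenin or estrogen response gene passed at either dose (medians -0.42 at 1 µg/L, camera adjusted p 0.2, and -0.14 at 0.01 µg/L, 0.736).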

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

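The tests of the metabolic, oocyte and interferon patterns below were chosen only after the result was seen, except for the fasting test and the counts of splits. Arrays far from the rest of their group were looked for in females at 1 µg/L, the one group of 4 arrays: of 66 genes and list scores checked, 6 had an array apart, where chance gives about 1 in 20.

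In females at 1 µg/L, replicate 2 stood apart for *slbp2* (-2.87 against a mean of -7.35 in the other arrays; the gap was 0.871 of the range), *nr1d1* (-3.01 against -1.49; 0.977), the cholesterol synthesis score (0.68 against -0.21; 0.84) and the circadian clock score (-0.44 against 0.12; 0.907). Replicate 4, the array of a single fish, stood apart for *gja2* (-2.82 against -4.41; 0.833) and the ribosome biogenesis score (-0.20 against 0.38; 0.83). No explanation of these arrays was tested.

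At 0.01 µg/L 7 genes passed a test of whether the change from control differed between the sexes: *smtla* (-3.77, at least 8.87-fold; females -1.6, males 2.17), zgc:173548 (-3.7; -1.5, 2.21), LOC100534848 (-3.38; -0.76, 2.62), TC434030 (-3.36; -1.76, 1.6), *nptna* (-2.78; -1.23, 1.56), *nmd3* (-2.2; -1.32, 0.87) and *slain1b* (-1.89, at least 3.64-fold; -1.82, 0.06). Of these, zgc:173548, LOC100534848 and TC434030 were named after their values were seen. At 1 µg/L *slain1b* passed this test (-3.01, at least 6.51-fold; -2.77 in females, 0.24 in males). *slain1b* and *smtla* were not well above background in a group of dosed females, so the folds are lower bounds, and the 1 µg/L value of *slain1b* was -0.3 with normexp (adjusted p 0.853). Of 100 splits, 9 gave as many genes as the 7 at 0.01 µg/L (highest other 934), and 12 as many as the 1 at 1 µg/L (highest other 356), so chance is not excluded for either count. The highest other counts were many times the real ones, and what those splits reflect was not tested. The control females had a slide to themselves, so a difference of that slide cannot be told apart from these results.

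For the dose counts, the share of splits of the pools that gave as many genes was under 0.05 at 1 µg/L over both sexes (1 of 100 splits as large, the real one; 1845 genes, highest other 18), in females at 1 µg/L (1 of 35; 512, highest other 154) and between the doses (1 of 100; 50, highest other 7). These shares were not adjusted over the counts tested. The splits treat pools as independent, so differences between tanks or slides are not excluded, here or below. At 0.01 µg/L over both sexes 100 of 200 possible splits were run. Of these, 2 gave as many as 227, the real one among them, a share under 0.05, but the other gave 934. That split set control females 1 and 3, the 0.01 µg/L female 3, control males 1 and 3 and the 0.01 µg/L male 2 against the rest. It called more genes than the labels did. Its named arrays had the lowest interferon scores of their sex among control and 0.01 µg/L arrays. These were -1.58 to -1 against -0.38 to 0.54 in females, and -0.38 to -0.07 against 0.01 to 1.27 in males. The same held for the lymphoid scores. These lists were picked after the scores were seen, and what the split reflects was not tested. The splits were too few for a share under 0.05 for females at 0.01 µg/L (3 of 10 as large; real 2, highest other 3), males at 0.01 µg/L (1 of 10; 191, 80), males at 1 µg/L (1 of 10; 311, 0) and control females against males (1 of 10; 1387, 61). For the lists, 93 of 100 splits gave as many as 7 at 0.01 µg/L (highest other 18) and 95 of 100 as many as 8 at 1 µg/L (highest other 21), so chance is not excluded.

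The 8 genes of fatty acid synthesis and glucose metabolism that passed at 1 µg/L (*acaca*, *elovl5*, *thrsp*, *slc25a1b*, *mid1ip1l*, *gck*, *tat* and, rising, *igfbp1b*) shifted by 2.09 on average in their own directions (SE 0.26). The genes and their directions came from this same contrast, so the size of the shift and its SE are no independent evidence of a change. With the oocyte and intestine scores as covariates the shift was 2.35 (SE 0.27), so these scores did not account for it on these arrays. Slide cannot be told apart from the dose: with slide as a block in males the shift was 1.99 (SE 1.19) against 2.25 (SE 0.38), and in females no slide joined the groups. A different feeding state stays open as well, since the median of 9 fasting genes was 0.33, between the bounds set in advance, with *cpt1aa* rising and *pdk4* falling. An effect of the dose on lipogenesis stays among the open explanations.

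The oocyte and ovary markers were lower at 1 µg/L. Their deviations from the group means went together, with a mean correlation of 0.56 (highest of 200 random lists 0.1). RNA of ovary in some arrays would give this, whatever its route, but the value is not particular to it. The correlation estimated by camera was 0.559 for this list, 0.532 for secreted hepatocyte proteins and 0.906 for ribosomal proteins. Random genes are therefore too weak a comparison to tell ovary RNA from other sources. Ovary taken along in the dissection of females does not by itself account for the male scores, since 4 male arrays scored above the female median of 0.61. For the female arrays it stays open, because the scores of males may have another source. The dose may lower these transcripts too (shift -2.21, SE 0.92; exact permutation p 0.0343). These last explanations do not exclude each other, and mixing of material between pools was not tested.

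The interferon list was higher at both doses. More immune cells cannot be told apart from induction of the genes: the interferon score rose by more than the myeloid and lymphoid scores in each of 4 comparisons, by 0.53 at the lowest (SE 0.38), and 1 of the 4 lay beyond 2 SE. RNA of other tissues stays open (mean shift 0.48, SE 0.24, with covariates, 0.88, SE 0.31, without). So does slide (in males 0.3, SE 1.13, as a block, 0.51, SE 0.45, without). An effect of the dose stays open as well.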

How the results depend on the processing

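The alternatives without the arrays highest in oocyte markers, with oocyte and intestine scores as covariates, and without the arrays whose quality value was out of range were chosen only after the results were seen, as tests of those results. The other alternatives were set before the data were examined, and "moved" below means a count more than 1.5 times higher or lower than the one reported. The cause was not tested except where a construction is named.

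Of 163 named gene results called, with 6157 alternative values, 4680 kept the direction and the call, 1476 lost the call and 1 reversed: *ccn6* in males at 1 µg/L stood at -0.16 with normexp (adjusted p 0.63). Of 183 named results not called, with 6931 alternative values, 353 gained a call and 103 changed sign, in 33 results. Of 585 alternative values of 15 called lists, 533 kept the direction and the call, 51 lost the call, and the oocyte markers at 1 µg/L reversed to 0.04 (adjusted p 0.353) with the covariates, which hold the score of that list itself. Of 67 results called at 1 µg/L over both sexes for genes named in that comparison, 34 were called with each of the 19 arrays left out in turn. At 0.01 µg/L 1 of 30 was.

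Values of uncalled genes that changed sign, over both sexes, were as follows; the cause was not tested. With normexp: at 0.01 µg/L *hbbe1.1* -0.05 and at 1 µg/L *abcc8* -0.15, *pcsk1* -0.2, *tnni2a.4* -0.25. With median scaling: at 0.01 µg/L *ccnb1* 0.01, *pla2g1b* 0.01. With probes above background in a whole group: at 1 µg/L *myhz1.2* 0.28. With the mean of probes: at 0.01 µg/L *srebf2* 0.3, *vtg3* 0.24, *plvapa* 0.04, *actc1b* 0.02 and at 1 µg/L *srebf2* 0.56, *vtg3* 0.12, *leap2* 0.13, *actc1b* 0.45. With array weights: at 0.01 µg/L *ccnb1* 0.18, *vtg3* 0.18, *sec61a1a* 0.14 and at 1 µg/L *tnni2a.4* -0.06. With weights by fish: at 0.01 µg/L *ccnb1* 0.07, *vtg3* 0 and at 1 µg/L *pcsk1* 0, *tnni2a.4* -0.14. Without the array of the single female: at 1 µg/L *pcsk1* -0.05, *tnni2a.4* -0.24. With the additive model: at 1 µg/L *tnni2a.4* -0.03. With the replicate block: at 1 µg/L *pcsk1* -0.05, *tnni2a.4* -0.24. With slide as a random block: at 0.01 µg/L *ccnb1* 0.02 and at 1 µg/L *tnni2a.4* -0.01. In the authors' table: at 0.01 µg/L *ccnb1* 0.04, *sec61a1a* 0, *pla2g1b* 0.04, *abcc8* 0.02 and at 1 µg/L *cenpf* 0.24. Without the 2 arrays highest in oocyte markers: at 0.01 µg/L *ccnb1* 0.35, *vtg3* 0.06 and at 1 µg/L *tnni2a.4* -0.06. With the covariates: at 0.01 µg/L *ccnb1* 0.22, *sec61a1a* 0.02, *mafa* -0.14, *apoa4b.2* -0.08 and at 1 µg/L *ccnb1* 0.82, *cenpf* 0.27, *nr1d1* -0.27, *insb* 0.31, *mafa* -0.19, *tnni2a.4* -0.38. Without the 3 arrays with a quality value out of range: at 0.01 µg/L *vtg3* 0.08, *sec61a1a* 0.11, *hbbe1.1* -0.09. Of these, *srebf2* at 1 µg/L passed with the mean of probes (adjusted p 0.0302). With 1 array left out at a time the lowest and highest values were, at 0.01 µg/L *sec61a1a* -0.16 to 0.11, *ccnb1* -0.9 to 0.79, *pla2g1b* -0.16 to 0.15, *amy2al2* -0.72 to 0.23, *sycn.2* -0.59 to 0.02, *ccne1* -0.84 to 0.15, *apoa4b.2* -0.09 to 0.19, *h1m* -1 to 0.37, *amy2al1* -0.24 to 0.01, *hbbe1.1* -0.03 to 0.16, *vtg3* -0.49 to 0.22, *sycp1* -0.86 to 0.26, *vtg7* -0.56 to 0.16 and at 1 µg/L *pcsk1* -0.05 to 0.19, *tnni2a.4* -0.24 to 0.23, *cenpf* -0.55 to 0.11, *slc37a4a* -0.01 to 0.25, *nr1d1* -0.07 to 0.48, *per1b* -0.43 to 0.03.

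The counts moved with the processing of the signal, and the cause was not tested. The normexp offset of 50 by itself shrinks fold changes of dim genes, and its part in the normexp counts was not separated. With normexp the counts were 5648 for 1 µg/L, 26 for 1 against 0.01 µg/L, 0 for females at 0.01 µg/L, 268 for females at 1 µg/L, 472 for males at 0.01 µg/L, 1198 for males at 1 µg/L, 0 for the sex difference of the 0.01 µg/L effect, 6455 for control females against males, 16 for lists at 0.01 µg/L and 13 for lists at 1 µg/L. With quantile normalization they were 14 for females at 0.01 µg/L and 1 for the sex difference of the 0.01 µg/L effect. With median scaling they were 7 for 1 against 0.01 µg/L, 335 for females at 1 µg/L, 78 for males at 0.01 µg/L, 181 for males at 1 µg/L and 0 for the sex difference of the 0.01 µg/L effect. In the authors' value table they were 0 for females at 0.01 µg/L, 516 for males at 1 µg/L and 4 for the sex difference of the 0.01 µg/L effect. With no filter on dim probes they were 19 for 1 against 0.01 µg/L and 4 for the sex difference of the 0.01 µg/L effect. With probes above background on all arrays, which tests fewer genes, they were 0 for females at 0.01 µg/L, 291 for males at 0.01 µg/L, 518 for males at 1 µg/L, 3 for the sex difference of the 0.01 µg/L effect and 0 for the sex difference of the 1 µg/L effect. The mean of the probes of each gene gave 6 for females at 0.01 µg/L. Testing each probe by itself, which raises the number of tests, gave 482 for 0.01 µg/L, 4424 for 1 µg/L, 340 for 1 against 0.01 µg/L, 26 for females at 0.01 µg/L, 1306 for females at 1 µg/L, 499 for males at 0.01 µg/L, 1269 for males at 1 µg/L and 2336 for control females against males. With outlier spots kept, and with probes above background in a whole group, no count moved. Without the array of the single female at 1 µg/L the counts were 5 for 1 against 0.01 µg/L, 4 for females at 0.01 µg/L and 8 for the sex difference of the 1 µg/L effect.

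The counts also moved with the model; the cause was not tested. Trend and robust moderation gave 7 for females at 0.01 µg/L and 2 for the sex difference of the 0.01 µg/L effect. Weights of arrays estimated from the data gave 1118 for 0.01 µg/L, 3262 for 1 µg/L, 1079 for 1 against 0.01 µg/L, 59 for females at 0.01 µg/L, 1111 for females at 1 µg/L, 1018 for males at 0.01 µg/L, 1828 for males at 1 µg/L, 130 for the sex difference of the 0.01 µg/L effect and 10 for the sex difference of the 1 µg/L effect. Weights by the number of fish gave 351 for 0.01 µg/L, 23 for females at 0.01 µg/L, 87 for males at 0.01 µg/L and 2 for the sex difference of the 1 µg/L effect. Fitting the sexes separately, with fewer arrays to estimate the spread, gave 0 for females at 0.01 µg/L, 22 for females at 1 µg/L, 0 for males at 0.01 µg/L and 1 for males at 1 µg/L. The additive model gave 8 for 1 against 0.01 µg/L. An adjusted p under 0.1, a looser threshold, gave 744 for 0.01 µg/L, 3512 for 1 µg/L, 206 for 1 against 0.01 µg/L, 22 for females at 0.01 µg/L, 1571 for females at 1 µg/L, 586 for males at 0.01 µg/L, 817 for males at 1 µg/L, 36 for the sex difference of the 0.01 µg/L effect and 2162 for control females against males.

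With the replicate number as a block (a paired fit) the counts were 7 for 1 against 0.01 µg/L, 287 for females at 1 µg/L, 70 for males at 0.01 µg/L, 158 for males at 1 µg/L, 0 for the sex difference of the 0.01 µg/L effect and 7 for the sex difference of the 1 µg/L effect. With slide as a fixed block, which could be fitted for 3 contrasts, they were 3 for 1 against 0.01 µg/L, 0 for males at 0.01 µg/L and 6 for males at 1 µg/L. None of the genes called with this block in males or between the doses was among those reported. With slide as a random block, whose estimated correlation was -0.107, they were 1401 for 0.01 µg/L, 4355 for 1 µg/L, 670 for 1 against 0.01 µg/L, 90 for females at 0.01 µg/L, 2155 for females at 1 µg/L, 954 for males at 0.01 µg/L, 1470 for males at 1 µg/L, 71 for the sex difference of the 0.01 µg/L effect, 10 for the sex difference of the 1 µg/L effect and 2655 for control females against males. A negative correlation narrows the errors of contrasts between slides, so these higher counts do not speak for the calls. The cause of the other moves was not tested.

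Without the 2 arrays highest in oocyte markers the counts were 37 for 0.01 µg/L, 12 for 1 against 0.01 µg/L, 128 for females at 1 µg/L, 0 for the sex difference of the 0.01 µg/L effect and 3 for the sex difference of the 1 µg/L effect. With the oocyte and intestine scores as covariates they were 927 for 1 µg/L, 15 for females at 0.01 µg/L, 35 for females at 1 µg/L, 414 for males at 0.01 µg/L and 604 for males at 1 µg/L. Without the 3 arrays with a quality value out of range they were 1 for 0.01 µg/L, 1036 for 1 µg/L, 0 for 1 against 0.01 µg/L, 5 for females at 0.01 µg/L, 12 for females at 1 µg/L, 6 for males at 0.01 µg/L, 78 for males at 1 µg/L and 3 for the sex difference of the 0.01 µg/L effect. These fits have fewer arrays or fewer degrees of freedom, and how far this alone moved the counts was not tested.

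Camera with an estimated correlation, and fry in its directional test, called 0 lists at 0.01 µg/L and 0 at 1 µg/L, against 7 and 8 with the preset correlation. The mixed test of fry, which asks for changes either way, called 14 and 21. Unadjusted gene counts in the limma fits were 3869 at 0.01 µg/L and 5921 at 1 µg/L at p under 0.05, 2363 and 4836 in females and 3518 and 3492 in males, 2930 between the doses, and 1944 and 1861 for the sex differences. The correlation of the fold changes of the doses was 0.216 with the control arrays split between the doses, against 0.606 with the controls shared.

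Leaving out 1 array at a time moved the counts over these ranges, lowest to highest: 0 to 15 for the sex difference of the 0.01 µg/L effect, 13 to 961 for 0.01 µg/L, 2 to 16 for females at 0.01 µg/L, 0 to 998 for males at 0.01 µg/L, 1 to 8 for the sex difference of the 1 µg/L effect, 2 to 98 for 1 against 0.01 µg/L, 976 to 2242 for 1 µg/L, 45 to 692 for females at 1 µg/L, 9 to 929 for males at 1 µg/L, 706 to 1861 for control females against males, 6 to 15 for lists at 0.01 µg/L, 6 to 12 for lists at 1 µg/L. The count at 1 µg/L stayed within 1.5 times of 1845 for 16 of the 19 arrays, and the list count at 1 µg/L for each. The lone arrays behind the ranges are named next, and the cause was not tested.

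Counts that moved by over 1.5 times, by the array left out (group and replicate number), were as follows. 0.01 µg/L: control female 1: 69, 3: 94, control male 1: 42, 2: 961, 3: 92, 0.01 µg/L female 2: 13, 3: 145, 0.01 µg/L male 1: 150, 2: 77, 3: 101, 1 µg/L female 3: 126, 1 µg/L male 1: 145, 3: 131. Females at 0.01 µg/L: control female 1: 5, 0.01 µg/L female 1: 16, 3: 4, 0.01 µg/L male 1: 5, 1 µg/L female 4: 4. Females at 1 µg/L: control female 1: 46, 3: 129, 0.01 µg/L female 2: 325, 0.01 µg/L male 2: 332, 1 µg/L female 1: 291, 3: 45, 1 µg/L male 1: 333, 3: 321. The sex difference of the 0.01 µg/L effect: control female 1: 0, 2: 0, 3: 12, control male 1: 1, 2: 1, 3: 0, 0.01 µg/L female 1: 1, 2: 1, 3: 2, 0.01 µg/L male 1: 4, 2: 0, 3: 0, 1 µg/L female 1: 3, 2: 15, 3: 4, 1 µg/L male 1: 0, 3: 0. The sex difference of the 1 µg/L effect: control female 1: 2, 3: 2, control male 2: 2, 1 µg/L female 1: 2, 4: 8, 1 µg/L male 2: 2. Control females against males: control female 1: 858, control male 1: 706, 3: 869. Lists at 0.01 µg/L: control female 1: 15, 2: 12, control male 2: 13. 1 µg/L: control male 1: 1100, 1 µg/L male 1: 976, 3: 1074. 1 against 0.01 µg/L: control male 1: 32, 0.01 µg/L female 1: 87, 2: 4, 3: 11, 0.01 µg/L male 1: 11, 2: 4, 3: 9, 1 µg/L female 1: 15, 2: 98, 3: 2, 4: 5, 1 µg/L male 1: 7, 2: 14, 3: 9. Males at 0.01 µg/L: control male 1: 0, 2: 998, 3: 21, 0.01 µg/L female 1: 123, 2: 79, 0.01 µg/L male 1: 60, 2: 7, 3: 39, 1 µg/L female 1: 65, 3: 54, 1 µg/L male 1: 82, 3: 62. Males at 1 µg/L: control male 1: 9, 2: 929, 3: 95, 0.01 µg/L female 2: 184, 0.01 µg/L male 3: 185, 1 µg/L female 3: 191, 1 µg/L male 1: 35, 3: 31.

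Signal over background limits the dim genes: on average 74.6% of probes were well above background, from 67.7% in females at 0.01 µg/L to 81.2% in males at 1 µg/L, and 161 of the 1845 genes called at 1 µg/L were not well above background in some group. On simulated data, 43 of 100 genes with a log2 fold change of 1 and 71 of 100 with 2 were called over both sexes, against 19 and 53 in females and 17 and 48 in males.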

Other observations

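The test of the clock genes was chosen only after the result was seen, and so was the choice of the scores tested here. *nr1d1* rose at 0.01 µg/L and stood at the control level at 1 µg/L. The other clock genes had a median absolute log2 fold change of 0.51 at 0.01 µg/L, at percentile 99.9 of 10000 random lists of like mean signal. Another time of day at sampling may therefore be a source of this pattern. The labels give no sampling time, and an effect of the dose on the clock was not separated from it.

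Exact permutation tests of the array scores within sex gave, at 0.01 and 1 µg/L, p = 0.02 and 0.07 for ribosome biogenesis (shifts -0.64 and -0.37), 0.05 and 0.0414 for fatty acid oxidation (0.29 and 0.35), 0.045 and 0.02 for interferon response (0.84 and 0.93), 0.84 and 0.0343 for oocyte markers (-0.21 and -2.21) and 0.51 and 0.104 for intestine markers (0.85 and 1.64). These p-values were not adjusted for the 5 scores. *mxb* differed between control sexes by -4.10 and lay at -7.42 to -4.72 in control females, the lowest level among the groups.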
